A study of Homo sapiens with 9 samples.

How the data were processed

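The series holds 9 RNA sequencing libraries of A549 cells, 3 each for DMSO, GSK591 and MS023. Per the labels, total RNA was freed of ribosomal RNA and made into paired-end libraries with random hexamers, and cells were treated for 7 days at 1 µM. A count table deposited by the authors holds read counts per gene for all libraries, without normalisation, as whole numbers that sum to between 31398075 and 51244525 per library. The authors also deposited 9 tables of FPKM (fragments scaled to gene length and library depth) in the layout of Cufflinks gene tables. The labels name cutadapt, STAR, featureCounts and DESeq2 with the genome build hg19. Their versions, the annotation, the strand setting and any filter are not given in the sources used here. Since the strand setting is unknown, counts of antisense and overlapping genes are uncertain.

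Groups and replicate numbers were taken from the labels. Of 51796 gene identifiers in the count table, 48523 took their symbol from the FPKM tables, 10 from a gene name table, and 3263 had none. Positions are those of the FPKM tables (hg19), and gene types for 45025 identifiers came from a GENCODE annotation of a later build, matched by identifier. A symbol with several identifiers counts once for each identifier.

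Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 18292. Libraries were scaled by TMM, and a quasi-likelihood model with group as its only term was fitted to all 9 libraries. The tests were GSK591 vs DMSO, MS023 vs DMSO, MS023 vs GSK591 and an F-test among the 3 groups. P-values were adjusted by Benjamini-Hochberg across genes, with a threshold of 0.05. Fold changes are fitted values, and the standard error of a log2 change is its size divided by the square root of F. All p-values are two-sided. Depths of this size leave few counts for genes under 1 CPM, so group counts are given for several genes where they are fewest. Reads are not independent molecules, and the errors cover amplification in PCR only as far as it varied between libraries.

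Before the data were examined, 25 gene lists, the tests, the alternatives and a rule for named genes were fixed. The rule takes the 10 largest increases and 10 largest decreases against DMSO, and the 6 largest each way between inhibitors. Genes needed an adjusted p under 0.05, a mean of at least 1 CPM over the 6 libraries compared, and no overlap between the groups' libraries. It adds up to 2 members each way per list and all PRMT enzymes and partners. Genes without a proper gene name were left out, and some genes that the rule takes are not reported here. Lists were tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation. Member counts are given over all genes tested and adjusted over the list alone. Fry was run as an alternative test of whether a list moves one way on balance.

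The lists were PRMT enzymes and partners, p53 targets, replication-dependent histones, G1/S, G2/M and mitosis, recombination, interferon response, NF-kB and cytokines, snRNP proteins, genes with detained or poison introns, hnRNP proteins, snoRNA hosts, ribosomal proteins, cholesterol, epithelial junctions, mesenchymal genes, NRF2 targets, ATF4 and unfolded protein response, hypoxia, lysosome, mitochondrial mRNAs, lung lineage, neuronal genes, and markers of leukocytes and of fibroblasts and endothelium. After the comparisons had been seen, 3 more lists were written and tested in all 3 comparisons, adjusted over these 9 tests. They were mucous and goblet cell genes, secretory pathway machinery, and liver-type plasma proteins. Later they were tested again without AGR2, S100P, ST6GALNAC1 and C3.

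Alternatives fixed with them were scaling by DESeq2 size factors (RLE) or by total counts, scaling without the 20 most abundant genes, no filter on low counts, a filter of 1 CPM in 3 libraries, libraries thinned to the smallest, a replicate block, each library left out in turn, only the 6 libraries compared, an adjusted p of 0.01, a test against a log2 change of 0.5 (glmTreat), DESeq2 1.42.0, another prior count, and limma on log2 FPKM with a pseudocount of 1 or 0.1 and with or without a filter of FPKM 1 in 3 libraries. Chosen after seeing the data were mitochondrial rRNA as a covariate, leaving out DMSO 1 and GSK591 3, leaving out genes without a symbol together with mitochondrial rRNA, and named genes in FPKM. Further looks at the data beyond the plan covered secretory genes, olfactory receptor genes, genes detected at equal depth, gene span, a later principal component against mitochondrial rRNA, genes in the FPKM tables alone, overlapping genes and levels of expression.

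Replicate numbers were checked for pairing between groups. Over 9 pairs with the same number, deviations from the group mean correlated across genes with r from -0.43 to 0.26, and no library correlated best with its own number in both other groups, so the samples were treated as unpaired. Pairs with other numbers reached 0.352 (DMSO 1 with GSK591 3), 0.349 (GSK591 2 with MS023 1) and 0.309 (DMSO 2 with MS023 1), so some deviations were shared between groups, and the cause was not tested. The analysis was tested on simulated counts with known changes and noise drawn independently per gene. In them 200 genes with a DMSO mean above 1 CPM were changed in GSK591, as many up as down. Recovery was therefore not measured for genes under 1 CPM, and the rates do not cover data in which most genes change, as here. For GSK591 vs DMSO, edgeR recovered 85% of genes changed 1.5-fold and 96% of those changed 2-fold, with 12 false among 193 calls, and made 0 calls where nothing was changed. DESeq2 recovered 87% and 95% with 34 false among 216 calls, and limma 88% and 95% with 13 false among 196. The shared DMSO controls were imitated in 20 simulations of unchanged groups. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Sex-linked transcripts were left out of the text, and other data of the study, such as proteomics, were not used here.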

Results

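RNA was sequenced from A549, an epithelial line from a human lung adenocarcinoma, after 7 days of treatment. One group received DMSO, the solvent control. A second received GSK591, an inhibitor of PRMT5, the main enzyme that places symmetric dimethylarginine on proteins. A further group received MS023, an inhibitor of the type I enzymes such as PRMT1 and CARM1, which place asymmetric dimethylarginine. Both inhibitors were used at 1 µM, and each group had 3 libraries made after removal of ribosomal RNA. Control plates were seeded with 0.2 and treated plates with 0.4 times 1e5 cells. In each comparison with DMSO the seeded number thus changed together with the treatment. The DMSO libraries held 33001030, 47387808 and 46901284 counts, the GSK591 libraries 31398075, 41052864 and 46109239, and the MS023 libraries 51244525, 38203250 and 42345238. Levels are given as CPM, counts relative to library size after TMM scaling, as mean ± SD (n = 3), and changes as fitted log2 values ± standard error from all 9 libraries. The labels describe RNA extracted in triplicate and do not say that the replicates came from separate cultures, so the p-values measure the spread between these libraries.

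Of 18292 genes tested, 14289 (78.1%) differed among the 3 groups (edgeR F-test, adjusted p under 0.05). The first principal component held 54.4% of the variance and the second 22.8%, and the plot of the libraries on these components separated the groups. Mitochondrial rRNA, a trace of what depletion left, reached 932.5 CPM in GSK591 replicate 3 and lay between 0.410 and 20.7 CPM in the other libraries. That library also had the lowest share of counts in protein-coding genes (89.6%). Among the controls, DMSO replicate 1 had the most mitochondrial rRNA, 20.7 CPM, close to the 17.5 CPM of GSK591 replicate 1. DMSO replicate 1 also stood apart on the third principal component (8.9% of the variance), at 37.9 against -13.7 and -12.0 for DMSO replicates 2 and 3. That component spread the other groups too. GSK591 replicates 1, 2 and 3 lay at -0.794, -23.4 and 16.9, and MS023 replicates 1, 2 and 3 at -18.7, 6.99 and 6.76. The cause was not tested. With DMSO replicate 1 and GSK591 replicate 3 left out, a choice made after seeing the data, 13930 genes differed among the groups.

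**Figure D1:**
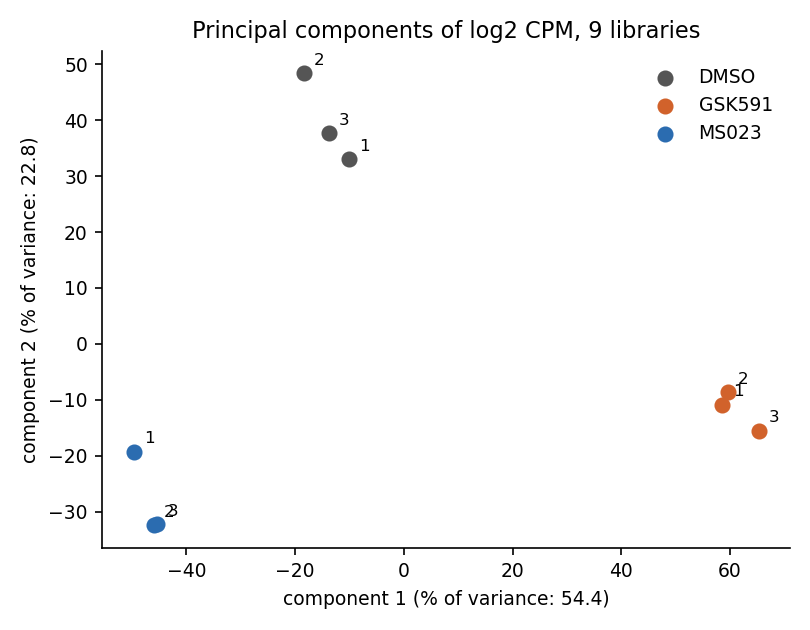
Each point is 1 library placed by its scores on the first and second principal components of log2 CPM, with axes labelled by the percent of variance and colours for DMSO, GSK591 and MS023. The 3 libraries of each group lie together, on axes that hold 54.4% and 22.8% of the variance.

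The targets of the inhibitors were compared first, at the level of RNA only. PRMT5 (ENSG00000100462, hg19 chromosome 14, 23389720 to 23398794) stood at 79.6 ± 4.65 CPM in DMSO and 80.8 ± 2.24 CPM in GSK591, a log2 difference of 0.02 ± 0.05 that did not pass the test (edgeR adjusted p = 0.700). PRMT1 (ENSG00000126457, hg19 chromosome 19, 50179043 to 50192286), the main type I enzyme of most cells, stood at 172 ± 9.07 CPM in DMSO and 186 ± 9.48 CPM in MS023, a log2 difference of 0.11 ± 0.05 that did not pass either (adjusted p = 0.0682). It passed without DMSO replicate 1 (adjusted p = 0.00806) or MS023 replicate 1 (0.0213), scaled by total counts (0.0173) and at a filter of 1 CPM (0.0333), among other settings, in a range of 0.00806 to 0.308 over the alternatives. PRMT1 RNA was lower in GSK591, at 127 ± 5.91 CPM, a log2 change of -0.43 ± 0.05 (adjusted p = 2.59e-06). PRMT5 RNA was slightly lower in MS023, by a log2 change of -0.16 ± 0.05 (adjusted p = 0.010). That call ended without DMSO replicate 1 (adjusted p = 0.0886) and in the authors' FPKM (adjusted p = 0.719), with a range of 0.00263 to 0.719 over the alternatives.

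Among 11 measured PRMT enzymes and PRMT5 partners, 8 fell and none rose in GSK591, with the same counts adjusted over the list alone. These were PRMT1, PRMT3 (-0.22 ± 0.04), CARM1, PRMT10, the PRMT5 partners WDR77 (-0.19 ± 0.05), CLNS1A (-0.26 ± 0.04) and COPRS (-0.21 ± 0.05), and RIOK1. As a list they did not stand apart from other genes (camera adjusted p = 0.0711). Without DMSO replicate 3 the list did (adjusted p = 0.0322). In MS023, CARM1 rose by 0.30 ± 0.06 and 5 members fell, namely PRMT3 (-0.44 ± 0.04), CLNS1A (-0.19 ± 0.04), PRMT5, PRMT2 and PRMT10, with the same counts adjusted over the list alone and camera adjusted p = 0.254. CARM1 in GSK591 lost its call without DMSO replicate 1 (adjusted p = 0.0534). The small change of RIOK1 in GSK591 lost its call in most alternatives, including RLE, DESeq2 and the loss of any 1 GSK591 replicate. Its adjusted p ranged from 0.0448 to 0.340. PRMT10 in GSK591 lost its call without any 1 of the GSK591 replicates (adjusted p = 0.0776, 0.108 and 0.0505), among other settings, with adjusted p up to 0.339. PRMT2 in MS023 lost its call in several alternatives, with adjusted p up to 0.531. PRMT10 in MS023 ended without DMSO replicate 2 (adjusted p = 0.134) or MS023 replicate 3 (0.0519) and in FPKM (0.275). The direct comparison of the inhibitors found PRMT1 (0.55 ± 0.05), CARM1 (0.51 ± 0.06), COPRS and WDR77 higher in MS023 and PRMT3, PRMT5 and PRMT2 lower (list adjusted p = 0.713). The call of WDR77 ended without GSK591 replicate 1 (adjusted p = 0.114) or 2 (0.105), without MS023 replicate 1 (0.0875) or 3 (0.139), in DESeq2 (0.0844), at a filter of 1 CPM (0.109) and scaled by total counts (0.0550), among other settings. That of PRMT2 ended without GSK591 replicate 1 (adjusted p = 0.0719) or 2 (0.0644), without MS023 replicate 2 (0.102) or 3 (0.0874) and in DESeq2 (0.111). In FPKM, PRMT2 was called in the opposite direction, higher in MS023 (log2 0.24, adjusted p = 0.00173), and PRMT5 had the opposite sign without a call (adjusted p = 0.403).

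The comparison of GSK591 with DMSO asks what a week of PRMT5 inhibition does to gene expression in these cells. CPA4, a secreted carboxypeptidase (ENSG00000128510, hg19 chromosome 7, 129932974 to 129964020), rose most among named genes, from 0.425 ± 0.121 to 22.2 ± 2.66 CPM, which is 51-fold (log2 5.67 ± 0.15, n = 3 per group). H19, an imprinted long non-coding RNA, fell most, from 105 ± 5.68 to 7.73 ± 1.38 CPM, which is 13.7-fold lower (log2 -3.78 ± 0.09). CDKN1A, which codes for the cyclin-dependent kinase inhibitor p21, rose 4.5-fold, from 58.5 ± 3.55 to 266 ± 1.52 CPM. The 62 measured genes of the replication-dependent histone list had a median log2 change of -1.68, and 61 of them fell (camera adjusted p = 1.57e-23, and adjusted p = 0.128 with an estimated correlation). Histones of this class are expressed in S phase. The list was taken by symbol, so it can hold other members, such as pseudogenes with symbols of the same form.

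Besides CPA4, the largest increases were CCND2, which codes for cyclin D2 (23.7-fold, from 11 counts over the DMSO libraries), SLAMF7 (17.3-fold, from 21 counts), PEAR1 (11.7-fold), the phospholipase PLA2G4C (11.5-fold), XDH, which codes for xanthine dehydrogenase (10.5-fold), the serotonin receptor HTR1F, the co-stimulatory receptor TNFRSF9, MARCH4 and CRISPLD2. These 10 had log2 changes of 3.30 to 5.67 with edgeR adjusted p of at most 9.63e-09. After H19 the largest decreases were CEACAM5 (11.9-fold, to 31 counts), TF, which codes for transferrin (7.53-fold), C9orf152, YBX2, CP, which codes for ceruloplasmin (5.74-fold), HTRA3, INSL4, the fibrinogen chain FGB (5.52-fold) and the iodide transporter SLC5A5. Their adjusted p were at most 5.72e-07, and in each of the 20 genes the 3 GSK591 libraries lay on one side of the 3 DMSO libraries.

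Of 35 measured p53 targets, 34 rose and MDM4 fell (-0.38 ± 0.04), with the same counts adjusted over the list alone and a median log2 change of 0.83. The death receptor FAS rose 4.0-fold, from 12.9 ± 0.332 to 51.3 ± 3.63 CPM. The list stood apart from other genes (camera adjusted p = 7.79e-17), and this call held with an estimated correlation (adjusted p = 0.0388). It was the only 1 of the 15 lists called in this comparison to do so. The fall of MDM4 lost its call in the authors' FPKM (adjusted p = 0.105), its highest over the alternatives.

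The histone genes included the linker histone genes HIST1H1B at -2.27 ± 0.06 and HIST1H1D at -2.24 ± 0.09. HIST2H2BD alone of the list did not pass. Reads of such near-identical genes are shared between copies, so single histone values are uncertain. Of 48 replication and G1/S genes, 46 fell (median -0.69), among them E2F8 (-1.39 ± 0.07) and RRM2, a subunit of ribonucleotide reductase (-1.35 ± 0.04), while CCNE1 rose (0.60 ± 0.05). That list had camera adjusted p = 6.96e-19 and adjusted p = 0.0919 with an estimated correlation. All 42 genes of G2/M and mitosis fell (median -0.95), including PTTG1, which codes for securin (-1.44 ± 0.06), and the topoisomerase TOP2A (-1.39 ± 0.04), with camera adjusted p = 4.99e-21 and adjusted p = 0.0919 with an estimated correlation. Of 38 genes of homologous recombination and the Fanconi pathway, 33 fell (median -0.63), including FANCI (-1.31 ± 0.04) and FANCD2 (-1.28 ± 0.04), and RAD50 rose (0.21 ± 0.04). Its camera adjusted p was 5.36e-12, and adjusted p = 0.0861 with an estimated correlation. Counts adjusted over the list alone were the same for these 4 lists.

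**Figure D2:**
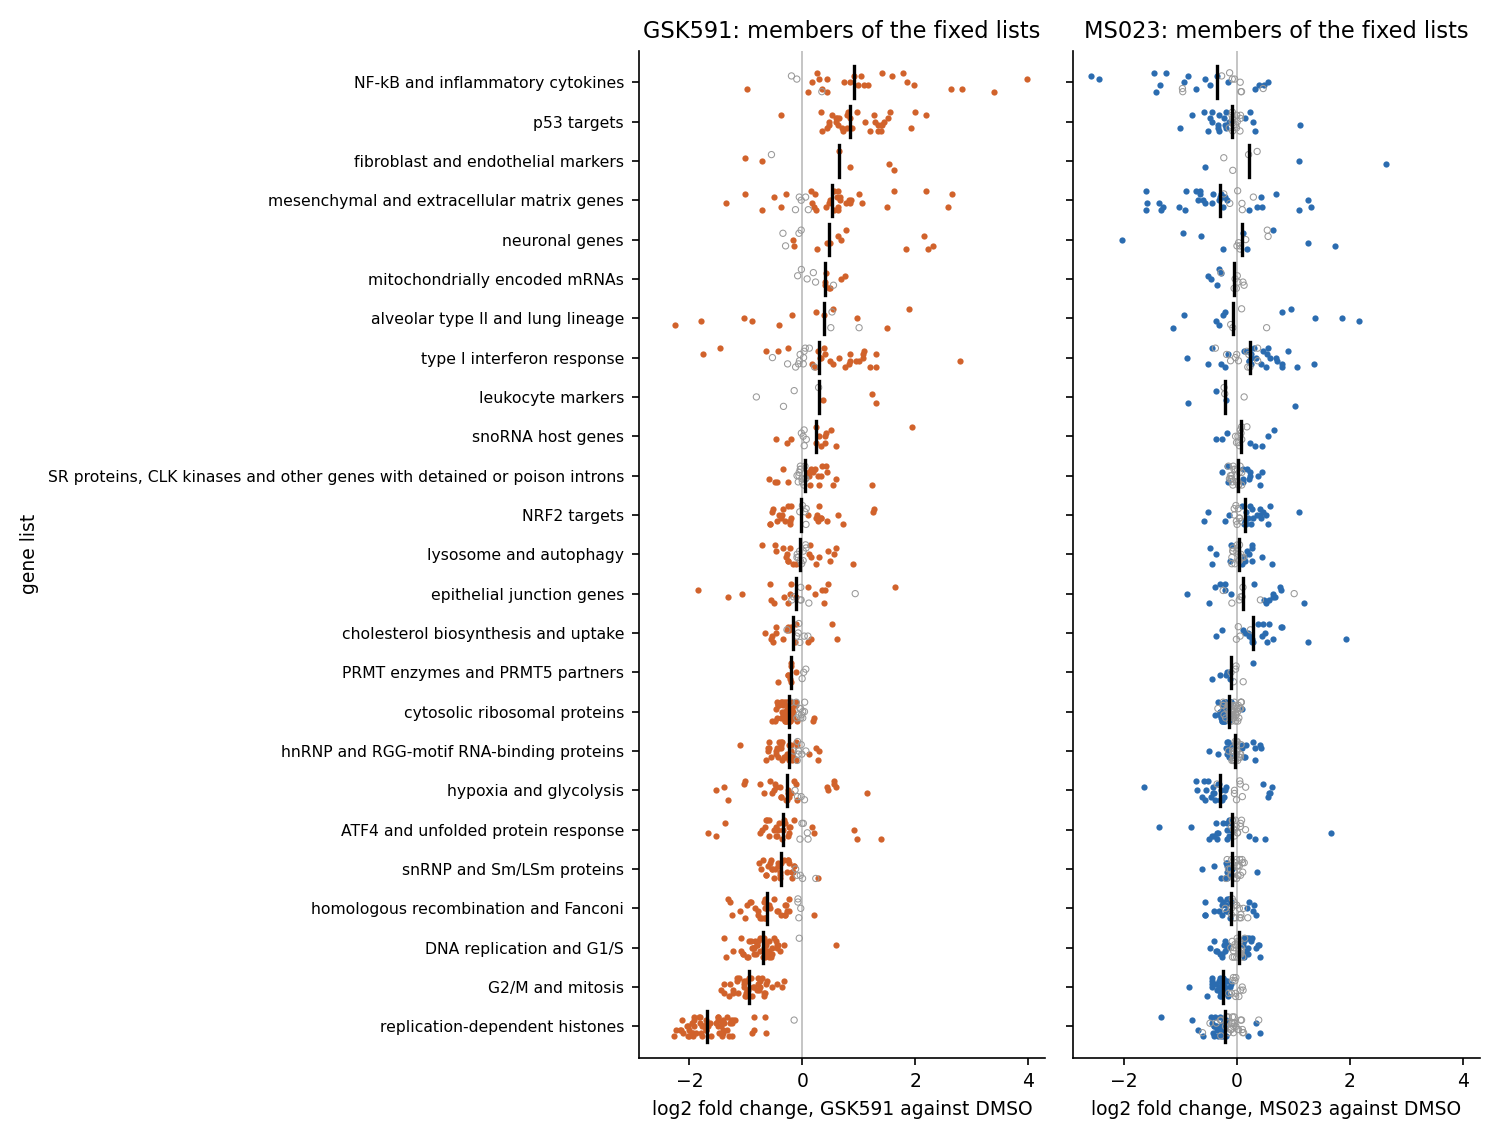
Fitted log2 change against DMSO (horizontal axis) of each tested member of the 25 gene lists (vertical axis), with 1 panel for GSK591 and 1 for MS023. Filled points passed the test, open points did not, and black lines mark medians, which lie at -1.68 and -0.21 for the histone list and at 0.83 and -0.08 for the p53 list.

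Of 27 NF-kB targets and cytokines, 23 rose (median 0.91), including TNFRSF9 (3.38 ± 0.23) and IL6, which had 2 counts over the DMSO libraries and 36 over the GSK591 libraries, while PTGS2, which codes for cyclooxygenase-2, fell (-0.99 ± 0.04). The list had camera adjusted p = 1.33e-06 and adjusted p = 0.108 with an estimated correlation. Of 38 mesenchymal and matrix genes, 27 rose and 6 fell (median 0.52), with the transcription factor SNAI1 at -1.35 ± 0.10. Its camera adjusted p was 6.31e-05, and adjusted p = 0.0919 with an estimated correlation. Of 40 interferon response genes, 23 rose (median 0.29), including TRIM22 (2.79 ± 0.15) and CMPK2 (1.30 ± 0.24), and 5 fell, ISG20 (-1.76 ± 0.09), IFITM1, OAS1, OAS3 and IFI35. Its camera adjusted p was 0.00312, and adjusted p = 0.0919 with an estimated correlation. Of 16 neuronal genes, 10 rose (median 0.46), including the cytoskeletal genes MAP2 (2.32 ± 0.06) and NEFL (2.22 ± 0.07), with camera adjusted p = 0.0125 and adjusted p = 0.102 with an estimated correlation. SNAP25 and ENO2 were slightly lower (-0.16 ± 0.05 and -0.14 ± 0.05), calls that ended without GSK591 replicate 1 (adjusted p = 0.0824 and 0.0846). Counts adjusted over the list alone were the same for the first 3 of these lists, and 10 and 3 for the neuronal genes.

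Of 36 snRNP and Sm/LSm genes, some of whose proteins are PRMT5 substrates, 30 fell (median -0.38), LSM7 by most (-0.77 ± 0.06), and SNRNP200 rose (camera adjusted p = 3.33e-06, and adjusted p = 0.220 with an estimated correlation). Of 46 hnRNP and RGG-motif genes, 34 fell (35 adjusted over the list alone, median -0.24), TAF15 by most (-1.11 ± 0.05), and 4 rose, among them FXR2, CIRBP and HNRNPH1 (camera adjusted p = 1.12e-04, and adjusted p = 0.220 with an estimated correlation). Of 77 cytosolic ribosomal protein genes, 63 fell (64 adjusted over the list alone, median -0.23), with camera adjusted p = 5.24e-04 and adjusted p = 0.694 with an estimated correlation. Single values of this family are uncertain because of its many processed copies. Of 35 ATF4 and unfolded protein response genes, 25 fell (median -0.34), including the transcription factor XBP1 (-1.66 ± 0.06), and 5 rose, SESN2 (1.39 ± 0.06), CHAC1, ATF3, PPP1R15A and DNAJB9, or 7 adjusted over the list alone. Its camera adjusted p was 4.44e-04, and adjusted p = 0.220 with an estimated correlation. Of 34 hypoxia and glycolysis genes, 24 fell and 6 rose (median -0.27), with PDK1 at -1.53 ± 0.06 and ADM at 1.14 ± 0.03 (camera adjusted p = 0.00623, and adjusted p = 0.514 with an estimated correlation). Of 24 genes of cholesterol synthesis and uptake, 13 fell and HMGCS1, TM7SF2, SC5D and SQLE rose (median -0.17, with 14 and 5 adjusted over the list alone, camera adjusted p = 0.0461, and adjusted p = 0.295 with an estimated correlation). That call ended without DMSO replicate 1 (adjusted p = 0.0626), DMSO replicate 2 (0.0621) or GSK591 replicate 2 (0.0626), and its adjusted p ranged from 0.0322 to 0.163 over the alternatives. HNRNPH1, FXR2, OAS1, OAS3, IFI35, ATF3, PPP1R15A, DNAJB9, SC5D and SQLE were named after their values were seen.

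Other lists did not stand apart from the rest of the genes in GSK591, and for each the counts adjusted over the list alone were the same. Genes with detained or poison introns, such as SR proteins and CLK kinases, had 16 of 34 members higher and 5 lower (camera adjusted p = 0.254), with CCNL2 at 1.24 ± 0.06 and SRSF4 at -0.58 ± 0.04. The snoRNA hosts had 10 of 18 higher and 3 lower (adjusted p = 0.0731), among them MEG3 at 1.94 ± 0.09. Without DMSO replicate 3 that list passed (adjusted p = 0.0322). Epithelial junction genes had 7 of 25 higher and 11 lower (adjusted p = 0.625), with KRT19 at 1.65 ± 0.07 and CLDN7 at -1.85 ± 0.16. NRF2 targets had 12 of 32 higher and 15 lower (adjusted p = 0.880), with HMOX1 at 1.27 ± 0.04. Their median was -0.02 and their mean 0.02. Lysosome and autophagy genes had 10 of 31 higher and 11 lower (adjusted p = 0.863), with median -0.04 and mean 0.01. Lung lineage genes had 6 of 15 higher and 6 lower (adjusted p = 0.950), with MUC5AC at -2.25 ± 0.12. Markers of other cell types did not pass as lists, with 3 of 7 leukocyte markers higher and none lower (adjusted p = 0.350), and 4 of 7 fibroblast and endothelial markers higher and 2 lower (adjusted p = 0.625). The leukocyte members were ITGAM, CD8A and, chosen after its values were seen, CD68. The 13 mitochondrially encoded mRNAs had 7 higher and none lower (adjusted p = 0.0805), with MT-ND5 at 0.69 ± 0.10. In the same comparison GSK591 replicate 3 carried the excess of mitochondrial rRNA, and without that library the list passed (adjusted p = 0.0460), as it did without DMSO replicate 3 (0.0291).

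In all, 11443 of 18292 genes (62.6%) changed in GSK591, 5510 higher and 5933 lower (edgeR, adjusted p under 0.05), with a median size of 0.46 among them. The balance depends on the scaling and the table, with 6286 higher and 5027 lower scaled by total counts, and 2788 higher and 5244 lower in the authors' FPKM with a pseudocount of 1. Without DMSO replicate 1 and GSK591 replicate 3 the count was 10564. At least 2-fold, 1666 genes were higher and 491 lower. In the authors' FPKM, 229 were higher and 256 lower by at least 2-fold on log2(FPKM + 1), which shrinks changes of low genes, and 502 and 421 with a pseudocount of 0.1, a smaller excess of increases.

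**Figure D3:**
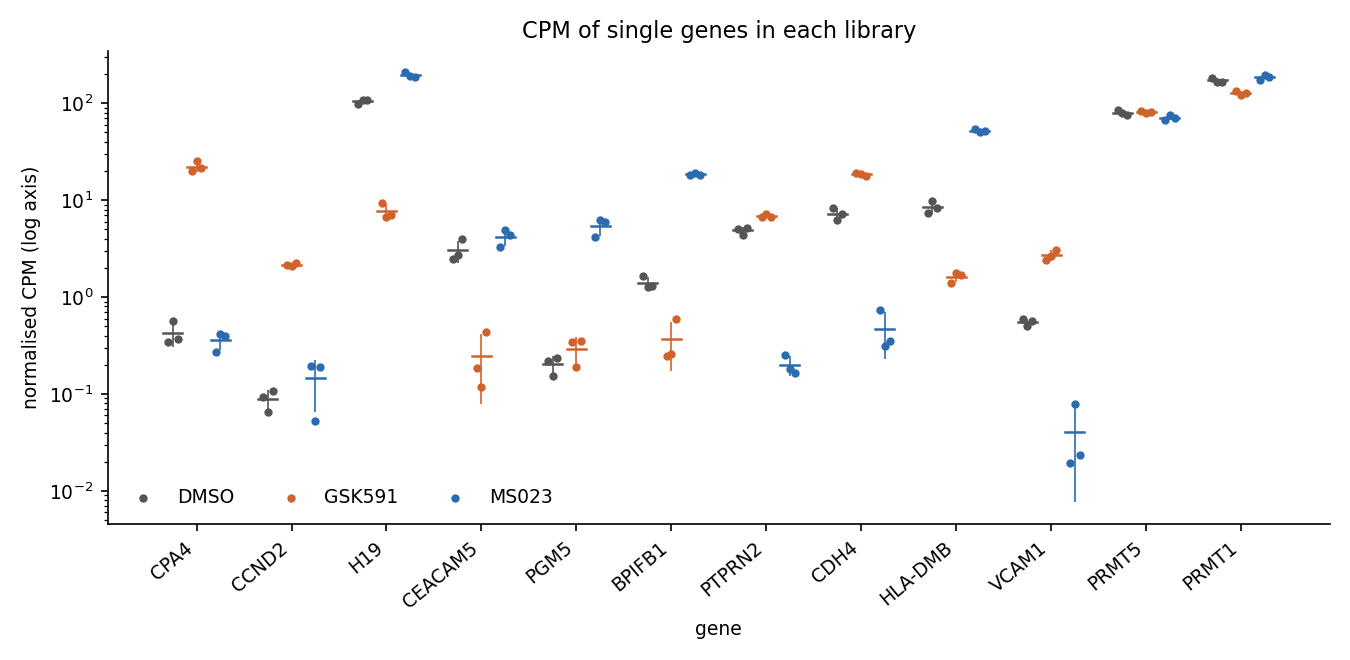
Normalised CPM (log axis) of 12 genes in each library of DMSO, GSK591 and MS023, with a point per library, a line at the group mean and error bars of 1 SD (n = 3). CPA4 stands at 0.425 CPM in DMSO, 22.2 in GSK591 and 0.363 in MS023.

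The comparison of MS023 with DMSO asks the same of type I PRMT inhibition. PGM5, a phosphoglucomutase-like protein of cell junctions (ENSG00000154330), rose most among named genes, from 0.203 ± 0.0452 to 5.47 ± 1.16 CPM, which is 26.6-fold (log2 4.74 ± 0.26, n = 3 per group, from 25 counts over the DMSO libraries). BPIFB1, a secreted protein of the airway, rose 13.4-fold, from 1.4 ± 0.22 to 18.6 ± 0.553 CPM. PTPRN2, a secretory granule protein of the tyrosine phosphatase family (ENSG00000155093), fell most, from 4.90 ± 0.419 to 0.200 ± 0.0472 CPM, which is 23.6-fold lower (log2 -4.56 ± 0.17, to 27 counts over the MS023 libraries).

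Next in size among the increases were the BMP antagonist GREM1 (11.8-fold), the neuronal kinesin KIF1A (11.0-fold), the adrenergic receptor ADRA2A (10.9-fold), SLC13A2 (9.61-fold), the cytochrome CYP2B6 (8.79-fold), LRRC36, AZGP1 and the somatostatin receptor SSTR2. Their edgeR adjusted p were at most 2.0e-07. The decreases went on with the cadherin CDH4 (14.6-fold), GGT5 (12.4-fold, to 23 counts), the serine protease HTRA3 (12.4-fold), the lipopolysaccharide-binding protein LBP (9.48-fold), NPTX1 (9.21-fold), SERPINA3, CD38, CHRDL2 and SDS, with adjusted p of at most 7.69e-09. HTRA3 was among the largest decreases of both inhibitors. In each of these 20 genes the 3 MS023 libraries lay on one side of the 3 DMSO libraries.

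Of 24 genes of cholesterol synthesis and uptake, 18 rose (19 adjusted over the list alone, median 0.28), while PMVK and HSD17B7 fell, the latter without a call in FPKM (adjusted p = 0.0586). The list had camera adjusted p = 4.01e-06 and adjusted p = 0.151 with an estimated correlation. Of 42 genes of G2/M and mitosis, 30 fell and none rose (median -0.24), or 32 and 1 adjusted over the list alone, with HMMR at -0.85 ± 0.05 and KIF20A at -0.52 ± 0.04 (camera adjusted p = 4.01e-06, and adjusted p = 0.480 with an estimated correlation). Of 62 histone genes, 29 fell and 3 rose (median -0.21), with the same counts adjusted over the list alone, camera adjusted p = 0.00748 and adjusted p = 0.771 with an estimated correlation. The 3 were HIST1H4A, HIST2H3A and, chosen after its values were seen, HIST1H4E. HIST2H3A lost its call without DMSO replicate 2 (adjusted p = 0.0963) or 3 (0.0616), without MS023 replicate 3 (0.226), in DESeq2 (0.151) and in FPKM (0.0693), and HIST1H4A in FPKM (0.144). Of 38 mesenchymal and matrix genes, 24 fell and 8 rose (9 adjusted over the list alone, median -0.29), with TGFBI and LOXL2 at -1.60 ± 0.03 and -1.60 ± 0.04 and CTGF at 1.26 ± 0.07 (camera adjusted p = 0.00522, and adjusted p = 0.260 with an estimated correlation). Of 40 interferon response genes, 22 rose and 6 fell (median 0.24), with the same counts adjusted over the list alone. OASL rose by 1.37 ± 0.15. The list's camera adjusted p was 0.0129, and adjusted p = 0.151 with an estimated correlation. Of 34 hypoxia and glycolysis genes, 21 fell and 5 rose (median -0.29), again with the same counts adjusted over the list alone, including the carbonic anhydrase CA9 (-1.65 ± 0.22) and PFKFB3 (0.63 ± 0.04). Its camera adjusted p was 0.0130, and adjusted p = 0.627 with an estimated correlation.

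Further lists were called less firmly. Of 35 p53 targets, 16 fell and 5 rose (median -0.08), with the same counts adjusted over the list alone. GDF15 rose (1.13 ± 0.06) and TP53I3 fell (-0.80 ± 0.04), with camera adjusted p = 0.0425 and adjusted p = 0.480 with an estimated correlation. Of 32 NRF2 targets, 19 rose and 4 fell (median 0.15), with the same counts adjusted over the list alone, GPX2 at 1.09 ± 0.06, camera adjusted p = 0.0407 and adjusted p = 0.480 with an estimated correlation. Of 77 ribosomal protein genes, 35 fell (34 adjusted over the list alone, median -0.14) and RPL23A rose slightly, with camera adjusted p = 0.0222 and adjusted p = 0.808 with an estimated correlation. The call of RPL23A ended without any 1 of the MS023 replicates (adjusted p = 0.0752, 0.0703 and 0.0558) and in FPKM (0.538). The p53 call ended without DMSO replicate 1 (adjusted p = 0.0619), DMSO replicate 2 (0.0771) or MS023 replicate 2 (0.0568), the NRF2 call without DMSO replicate 3 (0.0528) or any of the 3 MS023 replicates (0.0633, 0.0568 and 0.0542), and the ribosomal call without DMSO replicate 2 (0.130), MS023 replicate 2 (0.0610) or MS023 replicate 3 (0.0763). Over their alternatives the adjusted p ranged from 0.0279 to 0.0771, from 0.0118 to 0.0853 and from 3.61e-04 to 0.130.

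The NF-kB and cytokine list missed the threshold in MS023 (13 of 27 lower, with CXCL5 at -2.44 ± 0.05, 4 higher or 5 adjusted over the list alone, camera adjusted p = 0.0582). It passed without DMSO replicate 1 (adjusted p = 0.0397) or MS023 replicate 3 (0.0468), in a range of 0.0227 to 0.145. The remaining lists did not pass, and where no other count is given the counts adjusted over the list alone were the same. They were G1/S genes with 15 of 48 higher and 12 lower (adjusted p = 0.695, 13 lower adjusted over the list alone), homologous recombination with 5 of 38 higher and 18 lower (0.0844, with 7 and 19 adjusted over the list alone) and snRNP genes with 1 of 36 higher and 12 lower (0.242, with 11 lower adjusted over the list alone). Genes with detained or poison introns had 10 of 34 higher and 3 lower (0.608), hnRNP genes 10 of 46 higher and 12 lower (0.985, with 9 higher adjusted over the list alone), and snoRNA hosts 5 of 18 higher and 3 lower (0.325). Epithelial junction genes had 10 of 25 higher and 7 lower (0.140), ATF4 and unfolded protein response genes 4 of 35 higher and 17 lower (0.0928), and lysosome genes 10 of 31 higher and 5 lower (0.497). Mitochondrially encoded mRNAs had 5 of 13 lower (0.347), lung lineage genes 5 of 15 higher and 6 lower (0.920), and neuronal genes 5 of 16 higher and 4 lower (0.389). The lung lineage median was -0.07 and its mean 0.30. Leukocyte markers had 1 of 7 higher and 3 lower (0.389), and fibroblast and endothelial markers 2 of 7 higher and 1 lower (0.559). Named members of these lists included XBP1 (1.66 ± 0.06), which fell in GSK591, the mucin gene MUC5B (2.17 ± 0.12), MAP2 (1.74 ± 0.06) and SNAP25, a protein of vesicle fusion (-2.04 ± 0.06).

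In all, 9327 genes (51%) changed in MS023, 4594 higher and 4733 lower (edgeR, adjusted p under 0.05), with a median size of 0.37. Scaled by total counts, 5190 were higher and 4035 lower. Without DMSO replicate 1 and GSK591 replicate 3 the count was 9214. At least 2-fold, 779 genes were higher and 720 lower, against 466 and 413 at a filter of 1 CPM, and in FPKM 122 and 134 with a pseudocount of 1 and 319 and 316 with 0.1.

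The direct comparison of MS023 with GSK591 asks where the effects of both inhibitors, given at the same dose for the same time, differed. BPIFB1 was 48.4-fold higher in MS023 (SE 0.16 on the log2 scale, n = 3 per group), at 18.6 ± 0.553 CPM against 0.365 ± 0.194 CPM. HLA-DMB, which codes for a chain of the class II peptide-loading molecule HLA-DM, was 32.0-fold higher (5.00 ± 0.10), at 52.2 ± 1.85 CPM against 1.61 ± 0.192 CPM in GSK591 and 8.46 ± 1.18 CPM in DMSO. H19 was 25.6-fold higher (4.68 ± 0.09). CPA4 was 62.0-fold lower in MS023 (-5.95 ± 0.15), and XDH 39.3-fold lower (-5.30 ± 0.13).

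Further large differences were SLC13A2 (5.21 ± 0.26), AZGP1 (4.74 ± 0.32) and C9orf152 (4.44 ± 0.14), all higher in MS023, where GSK591 had 12 counts of SLC13A2 and 9 of AZGP1 over its libraries. Lower in MS023 were CDH4 (37.4-fold, -5.22 ± 0.17) and MYPN, which codes for a sarcomere protein (35.8-fold, -5.16 ± 0.12). The adhesion molecule VCAM1 had 332 counts over the GSK591 and 5 over the MS023 libraries, and CCBE1 had 315 and 7. Adjusted p of these 12 genes was at most 5.64e-09 (edgeR), and the libraries of the groups did not overlap in any of them.

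Of 35 p53 targets, 33 were lower in MS023 (34 adjusted over the list alone, median -1.07), with SPATA18 at -2.93 ± 0.09 and FAS at -2.44 ± 0.06, and MDM4 was higher (0.45 ± 0.04). The call (camera adjusted p = 8.27e-16) held with an estimated correlation (adjusted p = 0.0206), the only 1 of the 12 lists called here to do so. Of 62 histone genes, 60 were higher (median 1.49) and HIST2H2BC was lower, with camera adjusted p = 2.75e-18 and adjusted p = 0.197 with an estimated correlation. The call of HIST2H2BC ended with a replicate block (adjusted p = 0.0553), without any 1 of the GSK591 replicates (0.0529, 0.0931 and 0.0682), without MS023 replicate 1 (0.0977) or 3 (0.150), in DESeq2 (0.122) and in FPKM (0.135), among other settings. Of 48 G1/S genes, 46 were higher (median 0.78, E2F8 at 1.53 ± 0.07) and CCNE1 lower, with camera adjusted p = 1.23e-16 and adjusted p = 0.0949 with an estimated correlation. All 42 genes of G2/M and mitosis were higher (median 0.69, NEK2 at 1.17 ± 0.04), with camera adjusted p = 5.15e-15 and adjusted p = 0.116 with an estimated correlation. Of 38 recombination genes, 30 were higher (31 adjusted over the list alone, median 0.46) and RAD50, ATM and, named after their values were seen, BRCA2 and RAD51C lower, with camera adjusted p = 2.80e-07 and adjusted p = 0.0949 with an estimated correlation. Where no second count is given, counts adjusted over the list alone were the same.

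Of 27 NF-kB and cytokine genes, 24 were lower in MS023 (median -1.51, TNFRSF9 at -4.81 ± 0.27, with 20 counts in MS023) and PTGS2 was higher (1.32 ± 0.04), with camera adjusted p = 6.34e-09 and adjusted p = 0.0949 with an estimated correlation. Of 38 mesenchymal genes, 27 were lower (28 adjusted over the list alone) and 7 higher (median -0.88), with ACTA2, smooth muscle actin, at -3.08 ± 0.12 and COL1A1 at 1.81 ± 0.08 (camera adjusted p = 1.34e-05, and adjusted p = 0.0949 with an estimated correlation). Of 24 cholesterol genes, 18 were higher (19 adjusted over the list alone, median 0.47) and SC5D was lower (in FPKM adjusted p = 0.113), with camera adjusted p = 2.10e-05 and adjusted p = 0.0949 with an estimated correlation. Of 36 snRNP genes, 25 were higher and 4 lower (27 and 5 adjusted over the list alone, median 0.38, LSM7 at 0.90 ± 0.06), with camera adjusted p = 0.00110 and adjusted p = 0.356 with an estimated correlation. Of 46 hnRNP genes, 34 were higher and 5 lower (35 and 5 adjusted over the list alone, median 0.23, TAF15 at 1.19 ± 0.05), with camera adjusted p = 2.74e-04 and adjusted p = 0.305 with an estimated correlation. Of 13 mitochondrially encoded mRNAs, 11 were lower (median -0.48, MT-ND2 at -0.75 ± 0.10), with camera adjusted p = 0.0190 and adjusted p = 0.586 with an estimated correlation. GSK591 replicate 3, with mitochondrial rRNA of 932.5 CPM, did not carry more of these mRNAs than the rest of its group. They took 0.865% of its counts, against 0.940% and 0.920% in GSK591 replicates 1 and 2. Of 16 neuronal genes, 10 were lower and 4 higher, or 10 and 5 adjusted over the list alone (median -0.52, NEFL at -2.16 ± 0.07), with camera adjusted p = 0.0434 and adjusted p = 0.150 with an estimated correlation. That call ended without any 1 of the GSK591 replicates (adjusted p = 0.0870, 0.0547 and 0.0856) or MS023 replicate 3 (0.0732), in a range of 0.0144 to 0.0870. Where no second count is given, counts adjusted over the list alone were the same.

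Lists that did not pass in the direct comparison went both ways. Interferon genes had 12 of 40 higher and 19 lower (camera adjusted p = 0.255), with ISG20 at 1.76 ± 0.09 and TRIM22 at -2.42 ± 0.14. ATF4 and unfolded protein response genes had 19 of 35 higher and 12 lower (0.155), with XBP1 at 3.33 ± 0.06. NRF2 targets had 21 of 32 higher and 9 lower (0.161), epithelial junction genes 13 of 25 higher and 7 lower (0.161), and ribosomal protein genes 27 of 77 higher and 8 lower (0.251). Genes with detained or poison introns had 7 of 34 higher and 14 lower (0.517), snoRNA hosts 5 of 18 higher and 8 lower (0.594), hypoxia genes 16 of 34 higher and 11 lower (0.639), and lysosome genes 15 of 31 higher and 10 lower (0.707). Lung lineage genes had 6 of 15 higher and 5 lower (0.894), with MUC5B at 3.97 ± 0.13 and CAV1, which codes for caveolin-1, at -2.61 ± 0.05. Leukocyte markers had 1 of 7 higher and 4 lower (0.243), and fibroblast and endothelial markers 3 of 7 higher and 2 lower (0.894). Adjusted over the list alone, the counts differed for interferon genes (20 lower), ribosomal protein genes (24 and 5), lysosome genes (11 lower), lung lineage genes (6 lower) and leukocyte markers (2 higher).

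In all, 11955 genes (65.4%) differed between the inhibitors, 6151 higher and 5804 lower in MS023 (edgeR, adjusted p under 0.05), with a median size of 0.51. Scaled by total counts, 5837 were higher and 6014 lower, and in FPKM with a pseudocount of 1, 5298 and 3065. Without DMSO replicate 1 and GSK591 replicate 3 the count was 11550. At least 2-fold, 913 were higher in MS023 and 1963 lower, against 625 and 1170 at a filter of 1 CPM, and in FPKM 403 and 420 with a pseudocount of 1 and 669 and 716 with 0.1.

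The changes of both inhibitors against the same controls were then set side by side. Across genes, which are not independent replicates, the Pearson r of their log2 changes was 0.122. Simulated groups with no change, compared with shared simulated controls, gave a mean r of 0.497, between 0.445 and 0.527 in 20 simulations. Sharing controls sets that r in advance where nothing changes, so it is no reference for an r of groups that did change. The covariance was 0.0538 against a simulated 0.0197, a difference of 0.0341. Genes higher in both inhibitors numbered 1906, against 1384 for independent lists, and genes lower in both 2256, against 1535. Opposite calls numbered 1178 for genes higher in GSK591 and lower in MS023, against 1426, and 1265 for the reverse, against 1490. The shared controls raise the first counts and lower the others, and 3 controls were not split between the inhibitors to remove this. Control plates were also seeded with fewer cells than the plates of both inhibitors. An effect of seeding would move genes the same way in both, and it was not told apart from shared effects of the inhibitors. HTRA3, MAP2, SQSTM1 and HMMR were called in the same direction in both, and H19, XBP1, MUC5B and CAV1 in opposite directions. The r was 0.278 without DMSO replicate 1, 0.118 without DMSO replicate 2 and 0.205 without DMSO replicate 3. Having fewer shared controls can itself raise r, so these rises do not show that the inhibitors' effects are more alike.

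**Figure D4:**
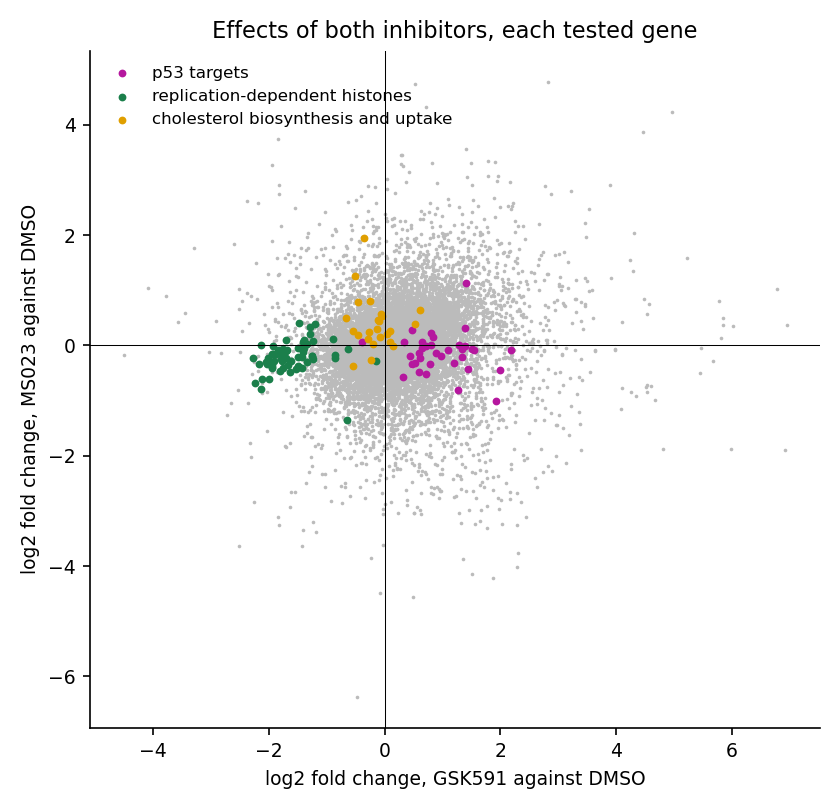
Fitted log2 change in MS023 against fitted log2 change in GSK591, each relative to DMSO, with 1 grey point per tested gene and colours for p53 targets, histones and cholesterol genes. The Pearson r across genes is 0.122, and the histones lie to the left, with a median of -1.68 in GSK591 and -0.21 in MS023.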

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

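Every test of an explanation in this part was chosen after the result it concerns was seen, as were the names of single genes from the FPKM tables.

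Genes whose identifiers are in the FPKM tables and absent from the count table were examined because the comparisons above hold no entry for them. Whether their reads were counted under another identifier was not checked. Of 9227 such genes, 639 passed the FPKM filter, and limma on log2(FPKM + 1) called 158 higher and 102 lower in GSK591 than in DMSO, and 136 higher and 85 lower in MS023. RHOT1P1, a pseudogene, had 3.23 ± 0.463 FPKM in GSK591 and 0.854 ± 0.147 in DMSO (SD, n = 3). CYP4F35P, a further pseudogene, had 1.39 ± 0.248 FPKM in GSK591 and 0.301 ± 0.105 in DMSO. MYO15B had 42.3 ± 4.26 FPKM in GSK591 and 22.7 ± 3.40 in DMSO. DGCR11 had 2.38 ± 0.161 FPKM in MS023 and 0.474 ± 0.0786 in DMSO. CORO7 had 8.81 ± 0.207 FPKM in MS023 and 4.79 ± 0.459 in DMSO. EGLN2 had 60.7 ± 1.37 FPKM in MS023 and 36.9 ± 1.11 in DMSO. Pseudogenes share reads with their parent genes, and other entries overlap annotated neighbours, so these values are uncertain.

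In GSK591, histone, G1/S and G2/M genes were lower and p53 targets higher than in DMSO, and the calls of the first 3 lists ended with an estimated correlation (adjusted p = 0.128, 0.0919 and 0.0919). Control plates were seeded with fewer cells than treated plates, yet MS023 plates were seeded like GSK591 plates and the histones differed between them by a median log2 of 1.49 (quartiles 1.23 to 1.68), which argues against the seeded number as the whole cause. A scaling error moves all genes alike, whereas the medians of p53 targets and histones lay 2.52 apart, with quartiles of 0.60 to 1.37 and -1.92 to -1.39. With mitochondrial rRNA in the model the histone median was still -1.51, which argues against leftover rRNA as the whole cause. Cell density at harvest is not given in the labels and stays open, and no biological explanation was tested.

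In GSK591, 2-fold increases (1666) outnumbered 2-fold decreases (491), most of all at low levels, with 647 increases and 98 decreases at a mean of at most 0.5 CPM and 130 and 162 over 20 CPM. Poor detection of decreases at low levels would also act on MS023, where the ratio at a mean of at most 0.5 CPM was 1.06 (245 and 232). Reads of overlapping tested genes would not reach protein-coding genes that overlap no other tested gene, where the ratio was 3.09 (822 and 266). In MS023 the ratio among those genes was 1.51 (484 and 320). Both explanations are thus argued against as the whole cause, while overlap with genes left out of the test was not examined. Genomic DNA in the GSK591 libraries would also raise silent genes, yet summed olfactory receptor CPM did not differ (ratio 0.989, 2.48 ± 0.350 against 2.51 ± 0.350 CPM). The sum rests on few counts, 67 to 130 per library over 397 genes, and argues against DNA as the whole cause. Genes of at most 0.5 CPM had a median log2 change of 0.42 in GSK591 and 0.01 in MS023. That shift is part of the excess itself and does not tell DNA from a change in the cells. At equal depth 26676 to 27321 genes were detected in the GSK591 libraries, 24839 to 26086 in DMSO and 25695 to 25800 in MS023. On its own that number does not tell DNA, against which the olfactory sum argues, from a change in the cells. The median of low genes was added to the test of DNA after the olfactory ratio had been seen, and with it that test gave no verdict. The excess was present after thinning to equal depth (1496 and 444) and at a filter of 1 CPM (946 and 328), and smaller among the 12784 genes with at least 1 FPKM (504 and 325). It was also present at 1 to 5 CPM (406 and 91) and 5 to 20 CPM (167 and 86). In the authors' FPKM it was absent with a pseudocount of 1 (229 and 256), which shrinks the changes of low genes and so decides nothing, and smaller with 0.1 (502 and 421). The cause of the excess stays open.

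Whether other groupings of the libraries give as many genes was asked for each comparison. The real groups gave 11443 genes in GSK591 vs DMSO against 0 in the highest of the other splits, 9327 against 3 in MS023 vs DMSO, and 11955 against 0 in MS023 vs GSK591, and 10 splits are too few for a share under 0.05, with 1 split (the real one) as large in each. For the F-test among the groups, 1 of 100 splits, the real one, reached 14289 genes, the smallest share that 100 splits can give. That argues against a random assignment of these libraries to groups as the source of the count. Relabelling libraries cannot address differences between plates or cultures, such as the number of cells seeded. The highest other split gave 7571 genes and kept the GSK591 libraries together while mixing DMSO and MS023.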

How the results depend on the processing

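Alternatives with mitochondrial rRNA in the model, without DMSO 1 and GSK591 3, without genes lacking a symbol, and named genes in FPKM were chosen after seeing the data, and the others before. Counts of called genes of any size stayed within 1.5 times under each scaling, filter, thinning, block, DESeq2 and left-out library. Without 1 library they lay between 10588 and 11273 for GSK591, 8012 and 9217 for MS023, 11211 and 11543 between inhibitors, and 13774 and 14470 among the groups. Tested against a log2 change of 0.5, 3257, 1797 and 4177 genes passed, since that test asks for a larger change. Changes of at least 2-fold numbered 2157, 1499 and 2876, against 1274, 879 and 1795 at a filter of 1 CPM, which leaves out low genes. In FPKM they numbered 485, 256 and 823 with a pseudocount of 1, and 923, 635 and 1385 with 0.1. For GSK591, counts limited to the 12784 genes with at least 1 FPKM held 504 increases and 325 decreases. The FPKM filter itself thus leaves out most of the 2-fold genes. With a pseudocount of 1 the GSK591 number was 479 without that filter, so there the filter is not what lowers it. For the other comparisons the cause was not tested. FPKM gave 5774 genes for MS023 with a pseudocount of 1, 5763 with 0.1 and 5470 without a filter, and the cause was not tested. With an estimated correlation, which reached 0.676 against the preset 0.01, 1, 0 and 1 lists passed. Fry, which asks another question, passed 15 for MS023 and 21 between inhibitors. The correlation between the inhibitors lay between 0.0948 and 0.278 without 1 library and was 0.068 with a filter of 1 CPM. A replicate block gave 11145, 8855, 11642 and 13946 genes and ended the GSK591 cholesterol (adjusted p = 0.0505) and MS023 NRF2 (0.0853), ribosomal and p53 (0.0572) calls. Signs turned in FPKM for SNHG3 (-0.23), SNHG15 (0.20) and ENO2 (0.00041) in GSK591, SNRPD3 (0.0254) and SNHG7 (-0.36) in MS023, and PRMT5 (0.0640), PRMT2 (0.24) and SNRPD3 (0.20) between inhibitors. Of these only PRMT2 (adjusted p = 0.00173) and SNRPD3 (0.0159) between inhibitors were calls in the opposite direction, and the cause was not tested. Fry called the lung lineage list lower in GSK591 (adjusted p = 0.00583) against a median of 0.39, and the cause was not tested. No scaling moved the median of all genes by over 0.1. Depth limits genes under 1 CPM, where few counts stand behind a value.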

Other observations

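Genes in this part were chosen after their values were seen, and the 3 lists were written after the comparisons had been seen and before their own tests were run. Leaving members out of them was chosen after those tests.

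Genes of mucous secretion moved apart in the inhibitors. MUC5B, a gel-forming airway mucin, fell in GSK591 (log2 -1.79 ± 0.13, n = 3 per group) and rose in MS023 (2.17 ± 0.12), and MUC5AC fell by far more in GSK591 (-2.25 ± 0.12) than in MS023 (-0.31 ± 0.11). SPDEF, a regulator of goblet cells, stood at 34.3 ± 1.73 CPM in DMSO, 9.65 ± 1.11 in GSK591 and 82.8 ± 3.95 in MS023. The transcription factors FOXA3 (-1.45 ± 0.10 and 1.76 ± 0.07), CREB3L1 (-1.02 ± 0.13 and 2.41 ± 0.10), XBP1 (-1.66 ± 0.06 and 1.66 ± 0.06) and FOXA1 (-1.03 ± 0.04 and 1.38 ± 0.04) fell in GSK591 and rose in MS023. So did AGR2, a chaperone of mucin folding (-1.38 ± 0.06 and 0.53 ± 0.06). The direct test between inhibitors passed for each of these genes, with edgeR adjusted p of 2.57e-09 for MUC5AC and less for the others.

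HLA-DMA rose in MS023 (2.58 ± 0.06) and did not pass in GSK591 (-0.14 ± 0.07, adjusted p = 0.0990), while HLA-DMB rose in MS023 (2.62 ± 0.08) and fell in GSK591 (-2.38 ± 0.11). CIITA, the regulator of class II genes, did not pass in MS023 (-0.05 ± 0.33, adjusted p = 0.921) and rose in GSK591 (0.84 ± 0.30, adjusted p = 0.0223). CD74, the class II invariant chain, did not pass in MS023 (-0.80 ± 0.34, adjusted p = 0.0629) or in GSK591 (0.44 ± 0.30, adjusted p = 0.218). Both were lower in MS023 than in GSK591 (CIITA -0.89 ± 0.29, adjusted p = 0.0155, and CD74 -1.23 ± 0.32, adjusted p = 0.00379), opposite to HLA-DMB. Both stood under 1 CPM in each group, CIITA at 0.282 ± 0.0558 in DMSO, 0.510 ± 0.123 in GSK591 and 0.276 ± 0.0393 in MS023, and CD74 at 0.632 ± 0.155, 0.881 ± 0.105 and 0.367 ± 0.205, so their changes rest on few counts. The nuclear non-coding RNA MALAT1 rose in GSK591 (1.15 ± 0.10) and in MS023 (0.51 ± 0.10). The complement gene C3 rose in GSK591 (0.38 ± 0.04) and fell in MS023 (-2.62 ± 0.05).

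A hypothesis drawn from these genes is that a mucous secretory program may move as a whole, down in GSK591 and up in MS023. The mucous list holds AGR2, named above, and the values of its members S100P and ST6GALNAC1 had been seen before it was written. Of 27 measured mucous and goblet cell genes, 19 were higher and 2 lower in MS023 than in GSK591, with a median log2 difference of 1.48, camera adjusted p = 2.16e-05 and adjusted p = 0.0165 with an estimated correlation. Against DMSO, 19 fell and 6 rose in GSK591 (median -0.91, adjusted p = 0.00413, and 0.0345 with an estimated correlation), and 17 rose and 3 fell in MS023 (median 0.51, adjusted p = 3.78e-04, and 0.0202 with an estimated correlation). The 6 that rose in GSK591 (TSPAN1, SYTL2, GALNT6, GCNT3, GALNT5 and MUC13) also rose in MS023. The 3 that fell in MS023 (CREB3L4, CEACAM6 and S100P) also fell in GSK591. Members such as TFF3 (0.0994 CPM in DMSO) and TSPAN8 (0.270 CPM), which moved in opposite directions, rest on few counts. Without AGR2, S100P and ST6GALNAC1, 24 genes had a median log2 difference of 1.22 between inhibitors (adjusted p = 3.95e-04, and 0.0231 with an estimated correlation). In MS023 that median was 0.48 (adjusted p = 4.91e-04, and 0.0231 with an estimated correlation). In GSK591 it was -0.80 (adjusted p = 0.0305), a call that ended with an estimated correlation (adjusted p = 0.0988). The list was higher in MS023 than in GSK591 or DMSO, while its fall in GSK591 is less firm. Some members moved the same way in both inhibitors, so the list did not move in opposite directions as a whole. The hypothesis was found and tested on the same libraries.

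Wider forms of the hypothesis stay undecided, and of the plasma proteins C3 had been seen before the list was written. Of 55 genes of the secretory pathway machinery, 28 were higher and 13 lower in MS023 than in GSK591 (median 0.12, camera adjusted p = 0.253), and in GSK591 against DMSO 31 fell and 8 rose (median -0.13, adjusted p = 0.0381, and 0.576 with an estimated correlation). In MS023 against DMSO 19 of them fell and 8 rose (median -0.06, adjusted p = 0.253). Of 22 liver-type plasma protein genes, 11 were higher and 6 lower in MS023 than in GSK591 (median 0.56, adjusted p = 0.451), 9 were higher and 7 lower in GSK591 than in DMSO (median -0.01, adjusted p = 0.851), and 12 were higher and 5 lower in MS023 than in DMSO (median 0.48, adjusted p = 0.126). Without C3 the list passed in MS023 against DMSO (median 0.52, adjusted p = 0.0305), and not with an estimated correlation (adjusted p = 0.465).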
